A study of Mus musculus with 4 samples.

How the data were processed

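Chromatin immunoprecipitation sequencing (ChIP-seq) of 2 histone modifications was analysed, trimethylated lysine 4 of histone H3 (H3K4me3) and trimethylated lysine 9 of histone H3 (H3K9me3). Per the labels, the cells were peritoneal macrophages of C57BL/6 mice aged 8 weeks, drawn out with thioglycollate broth, left to adhere in dishes and then kept for 24 h with lipopolysaccharide (LPS) or with phosphate-buffered saline (PBS). There were 4 samples in 4 groups, with 1 library for each mark and treatment, so no group had replicates.

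The submitters' processing notes name CASAVA 1.4, Bowtie 0.12.8, MACS 1.4.2, DiffBind and the mouse genome build mm10. Per the file headers, MACS called peaks in each library separately, with no control library, at a p threshold of 1e-05, with a band width of 300 bp, an effective genome size of 1.87e+09 bp and a local background window of 10000 bp. Per the file headers, at most 1 tag was kept at each position. Each deposited table gives for every peak its position, the count of tags in it, a score that the authors' caller computed as minus 10 times the base 10 logarithm of its p-value, and a fold enrichment, which is the caller's ratio of the peak to its background. The lowest scores listed were 50 in the H3K4me3 LPS and PBS libraries and the H3K9me3 PBS library and 50.01 in the H3K9me3 LPS library. A region that a list does not name was therefore under the caller's threshold in that library, which is not an absence of the mark. The score was used only to rank and filter peaks within a list, and the fold was not compared between libraries.

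The headers give 31391199 tags in all for H3K4me3 LPS, 37378032 for H3K4me3 PBS, 32859785 for H3K9me3 LPS and 33007219 for H3K9me3 PBS. After the caller's filter, 26748289, 29681491, 28586946 and 27727997 tags remained, and these filtered totals scaled all tag counts. At this depth the peaks with the fewest tags held 11 to 17, so a single weak peak has a wide counting interval. Intervals of shares and of single ratios are exact 95% Clopper-Pearson intervals, which cover counting error only. Intervals of a median are 95% intervals read from the ranked values of the regions or peaks. They reflect the spread among these and treat them as independent. Neither kind says how far another culture or immunoprecipitation would differ.

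Peaks on the primary chromosomes were used. Peaks of the LPS and PBS lists were called shared where they had at least 1 bp in common, and the counts were checked against bedtools 2.31.1. The lists of a mark were also merged into regions where peaks overlapped or touched. For each region with a peak of both lists, the log2 ratio of LPS to PBS tags per filtered tag was taken, with the length covered by peaks in each library beside it. Regions with at least 100 tags in both libraries together were counted when the ratio reached 2 in either direction. Because peaks were called separately, a sum of tags moves with the length that was called, so every ratio was also computed from tags per covered kb.

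Genes were taken from a RefSeq gene table of the assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes on the primary chromosomes. As a check of the match, 61.5% of these genes had an H3K4me3 peak of the LPS library within 1 kb of a gene end, against 14.5% when the genes were displaced by 50 kb and 9.95% when displaced by 1000 kb. The plan had been to use annotated transcription start sites. The gene table used here gives the outer ends of each gene and no strand, so a promoter was defined as the window within 1 kb of either gene end, the end with more tags over both libraries. H3K9me3 was assigned to the gene bodies that its peaks overlapped. Genes that share an end, such as divergent neighbours, can share a peak.

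With 1 library per group no test between treatments was possible, and no p-value across genes is given. Each ratio compares these libraries and not the conditions. There were 29 gene lists, fixed before the data were examined. They cover inflammatory mediators, interferon-stimulated genes, NF-kB signalling, antigen presentation, alternative activation, macrophage identity, resident peritoneal macrophages, LPS-linked metabolism, lipid handling, lysosome and phagocytosis, the cell cycle, the SUN and LINC complex, the nuclear lamina, H3K4 and H3K9 methylation enzymes, housekeeping genes, markers of 5 other cell types (T cells, B cells, neutrophils, eosinophils with mast cells, mesothelium with fibroblasts), neuronal genes, and 7 families or classes of genes (Hox, zinc finger, olfactory, vomeronasal, protocadherin, imprinted and germline genes). Each list was described by the median log2 ratio of its members with a peak in both lists, and by the percentile of that median among 10000 random lists of the same size matched on tags in 10 classes. Percentiles describe these libraries. H3K9me3 peaks on gene bodies were set beside random lists matched on gene length in 20 classes.

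The genes named in the text follow a rule set at the same time. For H3K4me3 it takes the 8 highest and 8 lowest promoter ratios among genes with at least 100 tags whose ratio per covered kb has the same sign (predicted genes left out), the 5 promoters of each single list with the most tags, and from each gene list up to 4 members with the largest absolute ratio and up to 4 with a peak in 1 list only. For H3K9me3 it takes the 5 regions with the most tags in each single list and list members on gene bodies. It also takes the 5 highest and lowest ratios among shared regions with at least 100 tags. The SUN and LINC list is named in full. Some genes that the rule takes are not reported here. The meeting of the marks was set beside 1000 random circular shifts of the H3K9me3 peaks within their chromosomes.

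The alternatives tried were a minimum of 50% of the peak covered, scores of at least 100, a distance of 1 kb, lists of equal length, tags per covered kb, a scale on which the median shared region or promoter is 0, no tag minimum, and a promoter window of 2.5 kb. The scoring of ratios and of lists was tested on simulated data before use. Poisson counts were drawn for the 13153 shared H3K4me3 promoters of the LPS and PBS comparison, 200 of them changed by known folds. The ratio of 2 was passed by 100% of the promoters changed 3-fold, 50% of those changed 2-fold and 2% of those changed 1.5-fold, and by 0 unchanged promoters. Of 100 simulated lists of 20 unchanged promoters, 3 fell in the outer 5% of the random lists, and all 100 did after a shift of 0.3 (log2). The simulation held counting error only, with no peak calling, no difference in called length and no general shift. It therefore does not measure the error that these bring to the real ratios. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.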

Results

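H3K4me3, a mark of active and poised promoters, and H3K9me3, a mark of heterochromatin and silenced repeats, were profiled in thioglycollate-elicited mouse peritoneal macrophages. The cells had been exposed for 24 h to LPS, the bacterial cell wall component that activates Toll-like receptor 4, or to PBS as the control. The title of the series names SUN proteins, which sit in the inner nuclear membrane and join the nucleus to the cytoskeleton through the LINC complex. The samples used here differ only in mark and treatment. Each of the 4 groups held 1 library, so differences between LPS and PBS have no replicate check. Intervals cover counting error only or, for a median, only the spread among regions or peaks. The filtered libraries held 26748289 (H3K4me3 LPS), 29681491 (H3K4me3 PBS), 28586946 (H3K9me3 LPS) and 27727997 (H3K9me3 PBS) tags. Peaks held 14.0% of the tags with H3K4me3 in LPS and 17.8% in PBS, but only 1.62% and 1.69% of the tags with H3K9me3.

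The first comparison asked where H3K4me3 differed between LPS-treated and PBS-treated macrophages. The LPS list held 28505 peaks and the PBS list 31398. Of the LPS peaks, 5638 (19.8%, 95% interval 19.3 to 20.2) met no PBS peak, and 8813 PBS peaks (28.1%, 27.6 to 28.6) met no LPS peak. The unmatched peaks were mostly weak, with medians of 27 tags in LPS and 33 in PBS against 109 and 156 for matched peaks. Scores under 100 belonged to 94.4% of the unmatched LPS peaks and 86.2% of the unmatched PBS peaks. With lists of equal length the counts were 6235 in LPS and 6570 in PBS, which the equal lengths by themselves hold close together. At peaks of score 100 or more, 316 LPS peaks and 1215 PBS peaks had no counterpart of any score in the other list. Both lists had a peak in 22219 merged regions.

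The median log2 ratio of LPS to PBS at those shared regions was -0.31 (interval of the median -0.31 to -0.30), a general shift towards PBS that was -0.15 in tags per covered kb. Among the 17893 shared regions with at least 100 tags, 100 were at least 2-fold higher in LPS and 570 at least 2-fold higher in PBS. Counting error alone around the median would give 0.01 and 20.9. On the scale where the median shared region is 0, the split was 267 higher in LPS and 155 higher in PBS, so the side with more regions depended on the scaling. In tags per covered kb only 1 region was 2-fold higher in LPS and 12 in PBS, a measure that depends on the length called in each library. At gene promoters the shift was -0.36. Medians of gene lists are given below relative to it. Ratios of single genes are given without that adjustment unless stated.

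Promoters of 13153 protein-coding genes carried H3K4me3 peaks in both lists. Interferon-stimulated genes, which cells switch on in response to type I interferon, had higher LPS to PBS ratios of H3K4me3 than other promoters did. Of the 37 listed genes found, 28 had a promoter peak in both lists, 0 in LPS only, 4 in PBS only and 5 in neither. Of the 28, 22 lay above the median of all promoters. The median log2 ratio of the 28 was -0.04 (quartiles -0.33 and 0.53), so the typical member was near level between LPS and PBS. This median was 0.33 above that of all promoters, the 100th percentile of random lists. The list median was 0.15 above that of all promoters in tags per covered kb (percentile 99.8) and 0.63 above it with a window of 2.5 kb. Oas2, a sensor of double-stranded RNA on chromosome 5 (120730333 to 120749886), had 323 tags in LPS and 128 in PBS (log2 ratio 1.49, 1.19 to 1.79). The nucleic acid sensor Zbp1 had 347 and 148 tags (1.38, 1.098 to 1.67), and Ifit1, which binds viral RNA, 207 and 106 (1.12, 0.77 to 1.47). The interferon beta gene Ifnb1 had 59 and 21 tags (1.64, 0.90 to 2.43). Per covered kb these 4 ratios were smaller, from 0.03 at Ifit1 to 0.25 at Oas2. Promoter peaks of Usp18, Gbp5, Ifit3 and Ifit2 were listed in PBS only, with 126, 93, 60 and 55 tags, although the LPS list had a peak within 5 kb of each. Neuronal genes, which macrophages do not use, lay higher still on the same scale (0.60 above all promoters).

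**Figure D1:**
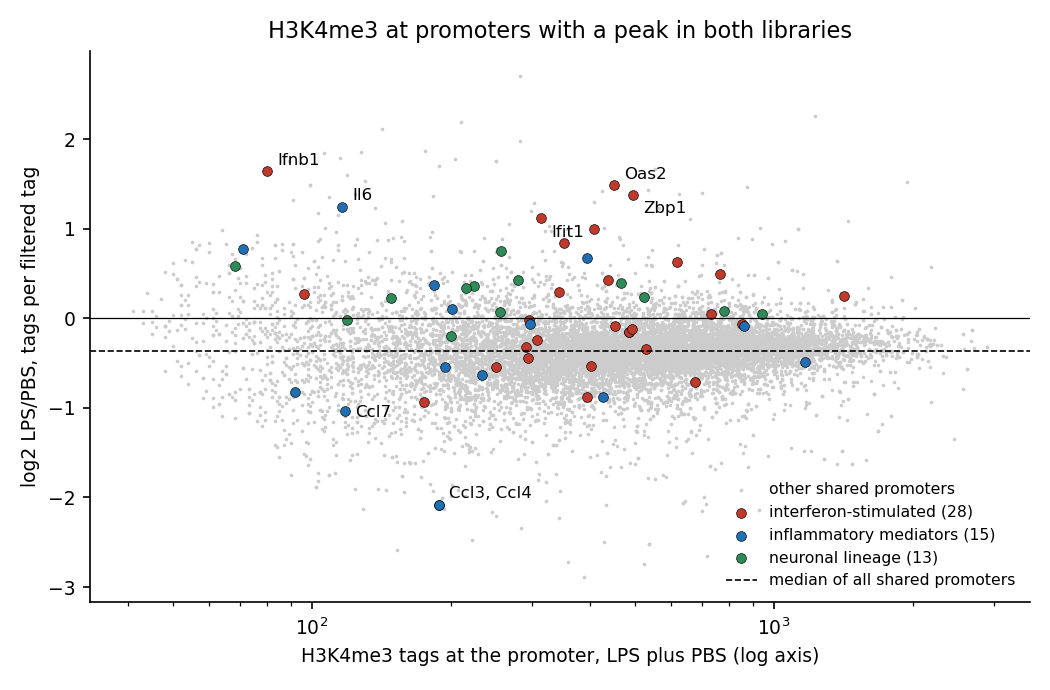
H3K4me3 tags at each promoter in both libraries together (x axis, log scale) against the log2 ratio of LPS to PBS tags per filtered tag (y axis). Each point is 1 gene with a peak in both lists, and 3 gene lists are coloured with the number of their genes in brackets. The dashed line is the median of all promoters at -0.36. Oas2, Zbp1, Ifit1, Ifnb1 and Il6 lie above 1, and Ccl3 and Ccl4, which were assigned the same peak, at -2.08.

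Inflammatory mediators went in both directions. Of 31 genes, 15 had a promoter peak in both lists, 6 in LPS only, 3 in PBS only and 7 in neither. The median of the 15 was 0.13 below that of all promoters (-0.13, percentile 14.2) in tags, but above it in tags per covered kb (0.22, percentile 99.7) and over whole merged regions (0.27), and further below it with a window of 2.5 kb (-0.23, percentile 0.95), so the list had no direction that held. Il6, the gene of interleukin 6 on chromosome 5 (30013114 to 30019975), had 79 tags in LPS and 37 in PBS (log2 ratio 1.24, 0.66 to 1.85), with a ratio of 0.49 per covered kb. The chemokine genes Ccl3 and Ccl4 on chromosome 11 were assigned 1 shared peak, with 33 tags in LPS and 155 in PBS (-2.08, -2.67 to -1.53). It covered 0.59 and 1.95 kb and gave -0.35 per covered kb. The annotated end of Ccl4 that was used (83648624) lies inside Ccl3 (83647843 to 83649378). The value may therefore not describe a promoter of Ccl4, although the list counts both genes. Ccl7 had 36 and 82 tags (-1.04, -1.65 to -0.46), and its sign changed per covered kb (0.23). Listed in LPS only were, among others, Lcn2, an iron-sequestering protein of the acute phase (210 tags, with 1 PBS peak within 5 kb), and Csf3, the granulocyte growth factor (202 tags). Tnf (348 tags) and Il10 (163 tags) had promoter peaks in PBS only, with 1 LPS peak within 5 kb of each.

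For the list of NF-kB feedback and signalling genes, 22 of 28 had a promoter peak in both lists. Their median was 0.10 above that of all promoters (percentile 94.65) and changed sign per covered kb (-0.13, percentile 0.43), while a window of 2.5 kb gave 0.16 (percentile 99.8). Nfkbia, the inhibitor of NF-kB, had 300 tags in LPS and 700 in PBS (log2 ratio -1.07, -1.27 to -0.88), and Nfkbiz 60 and 114 (-0.78, -1.25 to -0.31). Tnip1, a partner of the deubiquitinase A20, had 429 and 278 tags (0.78, 0.55 to 0.999). Irak2 had 153 and 99 tags (0.78, 0.40 to 1.16), with -0.79 per covered kb, where Tnip1 had 0.44, Nfkbiz -0.40 and Nfkbia -0.57. Antigen presentation genes had 16 of 21 members in both lists, with a median 0.24 above that of all promoters (percentile 99.97) that vanished per covered kb (-0.02, percentile 29.9). H2-DMa, which loads peptides onto class II molecules, had 951 tags over 5.62 kb in LPS and 498 over 1.76 kb in PBS (1.08, 0.93 to 1.24), and -0.59 per covered kb. Nlrc5, the activator of class I genes, had 316 and 219 tags (0.68, 0.43 to 0.93), and -0.53 per covered kb. B2m had 170 and 481 (-1.35, -1.61 to -1.10) and H2-Ab1 91 and 343 (-1.76, -2.11 to -1.43). B2m came to 0.04 per covered kb and H2-Ab1 to -0.56, and over merged regions to -0.40 and 0.02.

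The highest promoter ratios by the naming rule included Gpr183, an oxysterol receptor of immune cells, Hcar2, the niacin receptor, the transcription factor gene Sox2, and Parp11, Mall, Phf11a and Slfn1. They ran from 1.77 at Slfn1 to 2.71 at Gpr183 on chromosome 14 (121952331 to 121965193; 241 tags in LPS, 41 in PBS, interval 2.22 to 3.22). Per covered kb they ran from 0.06 at Gpr183 to 0.86 at Phf11a. Over whole merged regions Gpr183 came to 0.11 and Hcar2 to 1.21, because further PBS peaks lay beside the one at the gene end. The lowest included Eprs, a tRNA synthetase, Slc11a2, an iron transporter, Rps27l, Zfp33b, Mtrf1l and Rgs17, which share 1 peak, and Klf6. They ran from -2.89 at Eprs on chromosome 1 (185361417 to 185428360; 42 and 346 tags, -3.39 to -2.43) to -2.50 at Klf6 (59 and 371 tags, -2.92 to -2.10), and per covered kb from -1.46 at Eprs to -0.31 at Klf6. Over merged regions Klf6 stayed at -2.50, whereas the ratio was much smaller at the other genes named, with -0.34 at Slc11a2, -0.46 at Rps27l, -0.47 at Eprs and at Mtrf1l with Rgs17, and -0.86 at Zfp33b.

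A promoter peak was listed in LPS only for 275 genes and in PBS only for 685. The LPS-only promoters with the most tags were Ppp1r9b (1359), Tnfaip2, a gene induced by tumour necrosis factor (1205), Fam20c, a kinase of secreted proteins (985), Sema4c (865) and Trim8 (806). In PBS they were Git1 and Ankrd13b, which share 1 peak of 1439 tags, Ehbp1l1 (1223), Lrp1, an endocytic receptor (1201), and Zc3h12a, an RNase that degrades cytokine transcripts (1201). These peaks were wide, from 4.37 kb at Trim8 to 8.48 kb at Ppp1r9b. The scores in LPS ran from 53.7 at Ppp1r9b and 96.6 at Tnfaip2 to 406.8 at Trim8, and in PBS from 116.6 at Ehbp1l1 to 348.8 at Lrp1. The LPS peak at Sema4c met a PBS peak away from the gene end, with a ratio of -0.05 over the merged region, and the PBS peak at Ehbp1l1 met LPS peaks (-1.89). The housekeeping gene Actb (553 tags, PBS only) and Spi1, which encodes the macrophage factor PU.1 (503 tags, LPS only), each had 1 peak of the other list within 5 kb.

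Genes of macrophage identity and function stayed near the general shift. The median stood at -0.06 relative to all promoters for macrophage identity and pattern recognition (27 genes in both lists, percentile 8.67), 0.05 for alternative activation (11 genes, 63.8), 0.10 for resident large peritoneal macrophages (4 genes, 84.1), 0.01 for LPS-linked metabolism (17 genes, 43.2), -0.06 for lipid and cholesterol handling (19 genes, 7.37), -0.02 for lysosome and phagocytosis (19 genes, 19.4), -0.02 for the cell cycle (23 genes, 37.1) and -0.01 for housekeeping genes (18 genes, 39.9). Per covered kb the metabolism list was lower than matched lists (-0.15, percentile 0.17). Arg1, the arginase of alternatively activated macrophages, had 34 tags in LPS and 88 in PBS (log2 ratio -1.22, -1.84 to -0.64), and the mannose receptor gene Mrc1 129 and 271 (-0.92, -1.23 to -0.61). The adaptor Myd88 had 292 and 706 tags (-1.12, -1.33 to -0.92) but -0.03 over its merged region. The receptor Tlr3 had 34 and 109 (-1.53, -2.13 to -0.96). Gata6, the factor of resident peritoneal macrophages, had 443 and 534 (-0.12, -0.30 to 0.07). Hmox1, haem oxygenase 1, had 111 tags over 0.97 kb and 424 over 3.80 kb (-1.78, -2.10 to -1.48), and the lysosomal protease gene Ctsl 181 and 480 (-1.26, -1.51 to -1.01). Per covered kb Hmox1 came to 0.18, Ctsl to 0.22, Mrc1 to -0.11, Arg1 to -0.32, Myd88 to -0.39 and Tlr3 to -0.47. Among housekeeping genes, Polr2a had a ratio of -1.48 (-1.84 to -1.13), or -0.15 per covered kb, and Chmp2a of 1.11 (0.88 to 1.35), the latter -0.52 per covered kb and -0.69 over its merged region.

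Genes of the SUN and LINC complex did not stand apart. Of 11 genes, 8 carried a promoter peak in both lists and 3 in neither, and none in 1 list only. Their median was 0.09 above that of all promoters (percentile 85.8) and 0.07 per covered kb (percentile 79.5). Sun1, on chromosome 5 (139200564 to 139249839), had 327 tags in LPS and 453 in PBS (log2 ratio -0.32, -0.53 to -0.11) and Sun2, on chromosome 15 (79724068 to 79742536), 299 and 473 (-0.51, -0.73 to -0.30), or 0.04 and -0.15 relative to all promoters. Their partners of the outer nuclear membrane gave -0.46 for Syne2, -0.17 for Syne3, 0.19 for Kash5 (-0.09 per covered kb) and a value of 0 within counting error for Syne1 (97 and 108 tags, -0.42 to 0.40). Spag4 had -0.28 and Sun3 -0.26. Medians relative to all promoters were -0.07 for the nuclear lamina and envelope (13 genes, percentile 9.13), 0.05 for the H3K4 methylation machinery (14 genes, 73.9) and 0.07 for the H3K9 methylation machinery (19 genes, 90.4). Lmna, the lamin A gene, and Tmpo had promoter peaks in PBS only, with 125 and 97 tags.

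**Figure D2:**
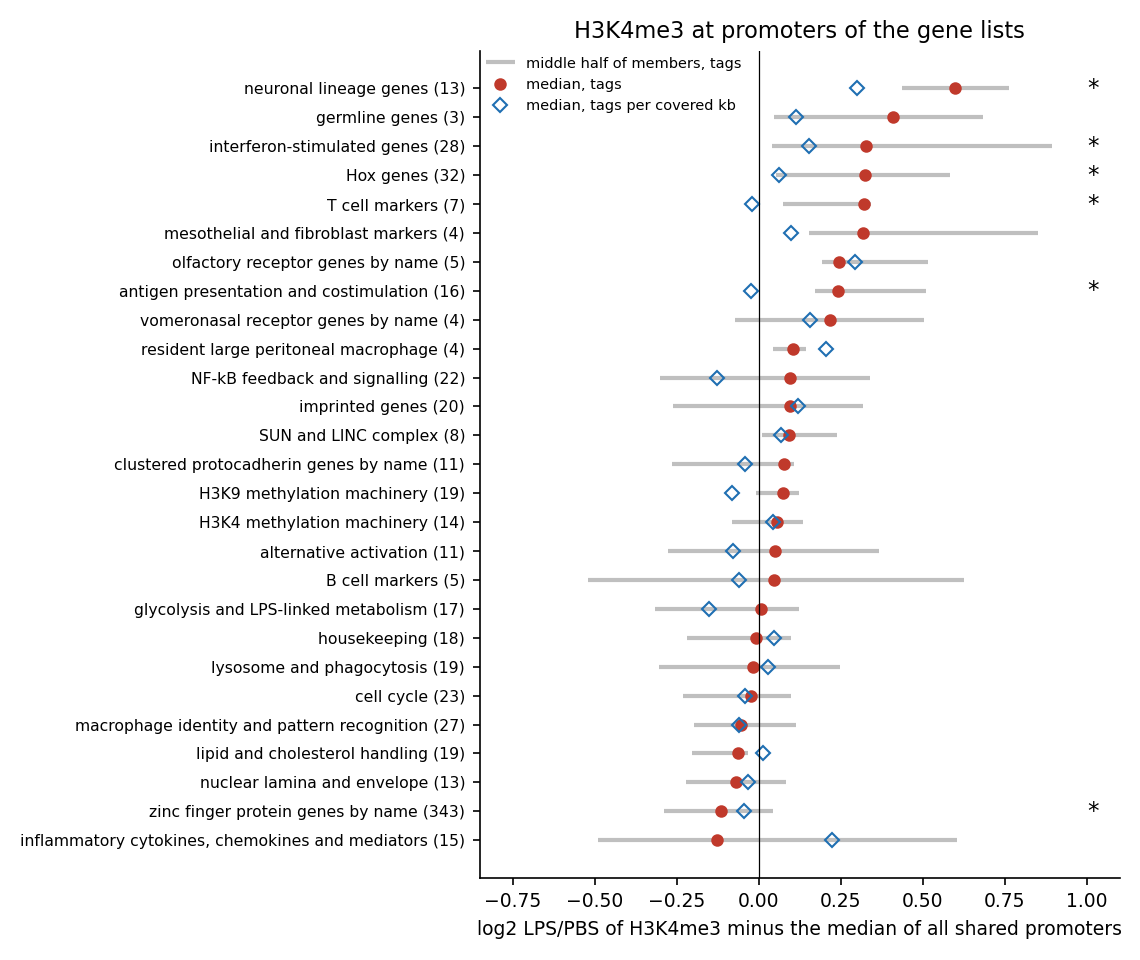
Median log2 ratio of LPS to PBS of H3K4me3 at the promoters of each gene list, minus the median of all shared promoters (x axis), for lists with at least 3 members that have a peak in both libraries (their number in brackets). Circles are medians of tags with a bar over the middle 50% of the members, diamonds are medians of tags per covered kb, and stars mark lists in the outer 5% of 10000 random lists, which takes in 5 lists above 0 (antigen presentation and T cell markers fall just below 0 per covered kb) and the zinc finger list below 0.

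Genes of other lineages were among the lists above the shift. Neuronal genes had 13 of 20 members with peaks in both lists, all 13 above the median of all promoters, and a median 0.60 above it (percentile 100; per covered kb 0.30, percentile 99.9). Grin1, a glutamate receptor subunit, had 254 tags in LPS and 214 in PBS (log2 ratio 0.40, 0.13 to 0.67), and Sox1 153 and 126 (0.43, 0.08 to 0.78), or 0.09 and 0.23 per covered kb. Hox genes, the patterning factors of the embryo, had 32 of 39 members in both lists. Their median was 0.33 above that of all promoters (percentile 100), and per covered kb 0.06 (percentile 87.5). Neighbouring Hox genes can share a peak, while random lists draw genes independently, so these percentiles can be too extreme. Hoxa10 had 409 tags over 5.35 kb in LPS and 143 over 1.53 kb in PBS (1.67, 1.39 to 1.95), with -0.14 per covered kb and 0.54 over its merged region. Hoxc5 had -1.49 (-1.96 to -1.04), and -0.07 per covered kb. Zinc finger genes lay below the shift, with 343 of 421 members in both lists and a median of -0.12 relative to all promoters, under all 10000 random lists (per covered kb -0.05, percentile 0.19). Zfp41 had 41 and 204 tags (-2.16, -2.69 to -1.68), with -0.76 per covered kb and -0.49 over its merged region. In all, 6 of the 27 lists with a percentile lay in the outer 5% of random lists, where chance gives 1.35, with 5 above and 1 under. Per covered kb it was 3 above and 3 under.

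Markers of other cells that a peritoneal lavage can hold were also examined. T cell markers had 7 of 15 promoters in both lists, with a median 0.32 above all promoters (percentile 99.3) that was lost per covered kb (-0.02, percentile 38.3) and lay at percentile 97.2 with a window of 2.5 kb. B cell markers had 5 of 12, with 0.05 (percentile 58.6). Of the neutrophil markers only Csf3r (0.09, -0.17 to 0.35; -0.10 per covered kb), and of the eosinophil and mast cell markers only Kit (-0.08, -0.36 to 0.20; 0.07 per covered kb), had peaks in both lists. The neutrophil markers Camp (56 tags) and S100a8 (21 tags) were listed in LPS only and Mmp8 (19 tags) in PBS only. Of 14 mesothelial and fibroblast markers, 4 had promoter peaks in both lists and 5 in PBS only, among them Upk3b (101 tags), Col1a2 (79), Krt8 (70) and Krt19 (33), with none in LPS only. Their shared members had a median 0.32 above all promoters (percentile 92.6). Pdgfrb had 188 and 62 tags (log2 ratio 1.75, 1.33 to 2.19), and -0.13 per covered kb. Olfactory and vomeronasal receptor genes, silent in most tissues, had 5 of 1110 and 4 of 353 promoters in both lists, with medians of 0.24 (percentile 79.4) and 0.22 (86.5) relative to all promoters. The medians were 0.08 for clustered protocadherins (11 genes, percentile 67.7), 0.10 for imprinted genes (20 genes, 93.9) and 0.41 for germline genes (3 genes, 91.8).

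The second comparison asked the same of H3K9me3. The LPS list held 17369 peaks and the PBS list 19279. The headers give the caller's estimate of fragment length (d) as 71 bp in LPS and 66 bp in PBS, against 149 and 142 bp for H3K4me3. The H3K9me3 peaks were also narrow, with median widths of 258 and 245 bp. Whether weak enrichment or a poor peak model lies behind these values was not tested, and it limits all H3K9me3 results below. More peaks were unmatched than matched. In LPS, 11155 peaks (64.2%, 63.5 to 64.9) met no PBS peak, and in PBS 13021 (67.5%, 66.9 to 68.2) met no LPS peak, with median tags of 16 and 15. Scores under 100 belonged to 93.5% and 94.97% of these unmatched peaks. With lists of equal length 11415 LPS peaks and 11389 PBS peaks were unmatched, counts that the equal lengths by themselves hold close together. The 6038 shared regions had a median log2 ratio of 0.03 (0.02 to 0.05) in tags and -0.03 in tags per covered kb, so no general shift held under both. Among the 862 shared regions with at least 100 tags, 59 were at least 2-fold higher in LPS and 18 in PBS. In tags per covered kb 0 and 1 regions were past 2-fold.

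Among the 862 shared regions with at least 100 tags, the highest H3K9me3 ratio was at the gene body of Fyb, an adaptor of immune cells. It lay on chromosome 15 (6527216 to 6534041, mm10). It had 697 tags over 6826 bp in LPS and 67 over 787 bp in PBS (log2 ratio 3.33, 2.97 to 3.72; 0.22 per covered kb). The next 4 overlapped Actr3b (2.42), Sim2 (2.10), Arhgap23 (2.07) and Unc5a (2.04), with 0.18, 0.52 and 0.24 per covered kb at the last 3 and -0.0050 at Actr3b. The lowest of these regions was one of 390 bp in Ctnnb1, the beta-catenin gene, on chromosome 9 (120950430 to 120950819). It had 20 and 90 tags (-2.21, -2.99 to -1.50) and -2.02 per covered kb. The Ctnnb1 region and the 5 regions with the highest ratios all overlapped an H3K4me3 peak of LPS or PBS. Whether background signal at H3K4me3-rich chromatin lies behind their ratios was not tested. The LPS-only region with the most tags was in Plec on chromosome 15 (76177553 to 76182468, 696 tags). In PBS it was in Sfi1 on chromosome 11 (3170456 to 3173080, 771 tags), and an LPS-only region of 319 tags lay in the same gene at 3165232 to 3166219. A further LPS-only region overlapped Sp110 and Sp140 on chromosome 1 (85599822 to 85601417, 258 tags), and also an H3K4me3 peak. On the same chromosome a PBS-only region with more tags overlapped A530032D15Rik (85085744 to 85088875, 544 tags).

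On gene bodies, H3K9me3 peaks were present in both lists for 3525 genes, in LPS only for 2299 and in PBS only for 1831. Imprinted genes, expressed from 1 parental copy, stood out. Of 28 found, 18 carried H3K9me3 in both lists, against 6.11 in random lists of like gene length (percentile 100), and 15 carried a site with both marks in each treatment. Among them, Nnat had 88 tags in LPS and 25 in PBS (log2 ratio 1.77, 1.12 to 2.47), Grb10 78 and 28 (1.43, 0.79 to 2.11), Inpp5f 54 and 105 (-1.003, -1.50 to -0.52) and Peg10 32 and 62 (-0.998, -1.66 to -0.36). Per covered kb Nnat came to 0.20, and the signs changed at Grb10 (-0.03), Inpp5f (0.01) and Peg10 (0.23). Zinc finger genes, many of which lie in clusters known to carry H3K9me3, had it in both lists at 126 of 421 genes against 58.7 (percentile 100). Their median log2 ratio was -0.26 relative to all marked genes (percentile 0.05; per covered kb 0.43), and Zfp930 (26 and 118 tags, -2.23, -2.90 to -1.60) and Zfp607a (27 and 108 tags, -2.04, -2.71 to -1.42) had the lowest values, which came to -0.10 and -0.05 per covered kb. Germline genes had H3K9me3 in both lists at 6 of 20 against 2.62 (percentile 98.1), with Ddx4, Sycp1, Mael and Tdrd1 among them, and housekeeping genes at 5 of 20 against 1.89 (percentile 98.0). Of the interferon-stimulated genes 0 of 37 had it in both lists, against 3.32 (percentile 1.57), with 5 in LPS only and 1 in PBS only, and of the olfactory and vomeronasal receptor genes 0 of 1110 and 4 of 353, against 18.7 and 19.5 (percentile 0 for both).

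**Figure D3:**
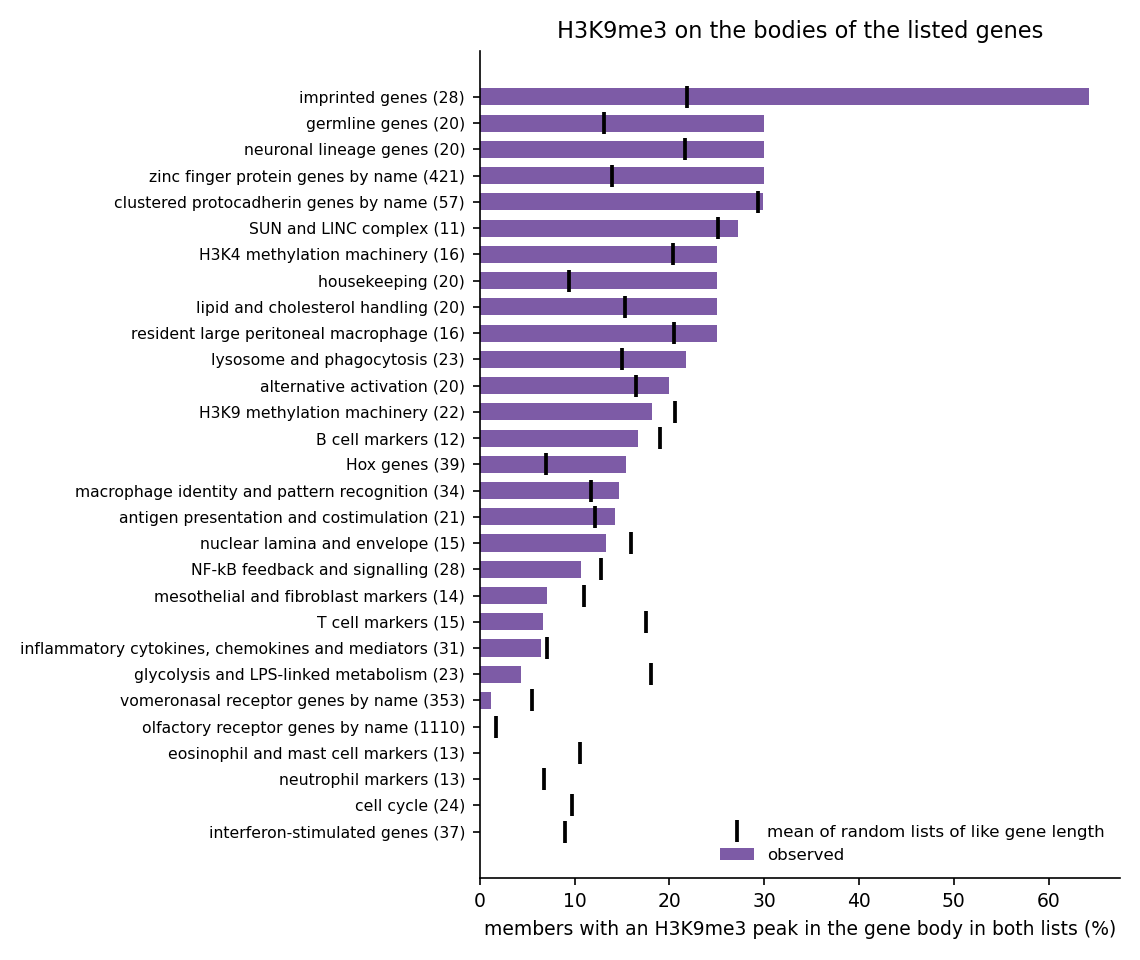
Share of the genes of each list that had an H3K9me3 peak in the gene body in both the LPS and the PBS library (bars, percent; number of genes in brackets), with the mean of random lists of like gene length as a black tick. Imprinted genes reach 64.3%, and zinc finger and germline genes lie above their ticks.

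Among Hox genes, 15 had H3K9me3 in LPS only, 2 in PBS only and 6 in both lists. The LPS-only and PBS-only counts were 7 and 1 for NF-kB signalling, 7 and 1 for LPS-linked metabolism, 47 and 65 for zinc finger genes and 2299 and 1831 for all genes, and no difference between such counts was tested. The LPS-only Hox genes included Hoxa3 (103 tags), Hoxa10 (53), Hoxa5 (52) and Hoxa11 (51), which lie in 1 cluster on chromosome 6, so they are not independent. The whole LPS list also held more peaks near gene ends (18.6% against 13.2%). Of the SUN and LINC genes, Sun5 (67 and 65 tags), Syne1 (37 and 63) and Syne3 (38 and 25) had an H3K9me3 peak in both lists, and Syne2 (32 tags) and Sun1 (12 tags) in LPS only. Their median ratio lay at the 39.6th percentile over 3 genes. The resident peritoneal macrophage list had the highest H3K9me3 median, 1.18 above all marked genes over 4 genes (percentile 98.7). Gata6 (64 and 20 tags, log2 ratio 1.63, 0.89 to 2.44), Alox15 (72 and 27 tags, 1.37) and Rarb (110 and 47 tags, 1.18) lay above 0 and Selp (51 and 60 tags) at -0.28. Per covered kb Gata6 came to 0.01 and the list to percentile 82.0. Of the 18 lists with a percentile, 2 lay in the outer 5%, where chance gives 0.9.

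The last comparison asked how often the marks met. In LPS 5365 H3K4me3 peaks (18.8%, 18.4 to 19.3) overlapped an H3K9me3 peak, against 296.6 after shifting the H3K9me3 peaks. In PBS 3954 (12.6%, 12.2 to 13.0) did so, against 364.8. Of the H3K9me3 peaks, 33.7% (33.0 to 34.4) lay on an H3K4me3 peak in LPS and 22.4% (21.8 to 23.0) in PBS, a difference beyond counting error that has no replicate check. The overlap was greatest at the strongest H3K9me3 peaks. Of the 1000 with the highest scores, 85.7% lay on an H3K4me3 peak in LPS and 73.5% in PBS, and 606 and 553 of these were not within 1 kb of a gene end. Hox genes had such a site in 20 of 39 gene bodies in LPS (4.79 in random lists, percentile 100) and in 9 in PBS (3.43, percentile 99.7). These random lists were matched on gene length and not on H3K4me3. A promoter peak in both H3K4me3 lists was found for 32 of 39 Hox genes, against 60.1% of all coding genes. Neighbouring Hox genes can also share a site, so these percentiles can be too extreme. Other lists lay high too, with neuronal genes at 9 in LPS (3.99, percentile 99.5) and the H3K4 methylation machinery at 7 in PBS (2.84, percentile 99.2). Interferon-stimulated, olfactory and vomeronasal genes lay low.

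**Figure D4:**
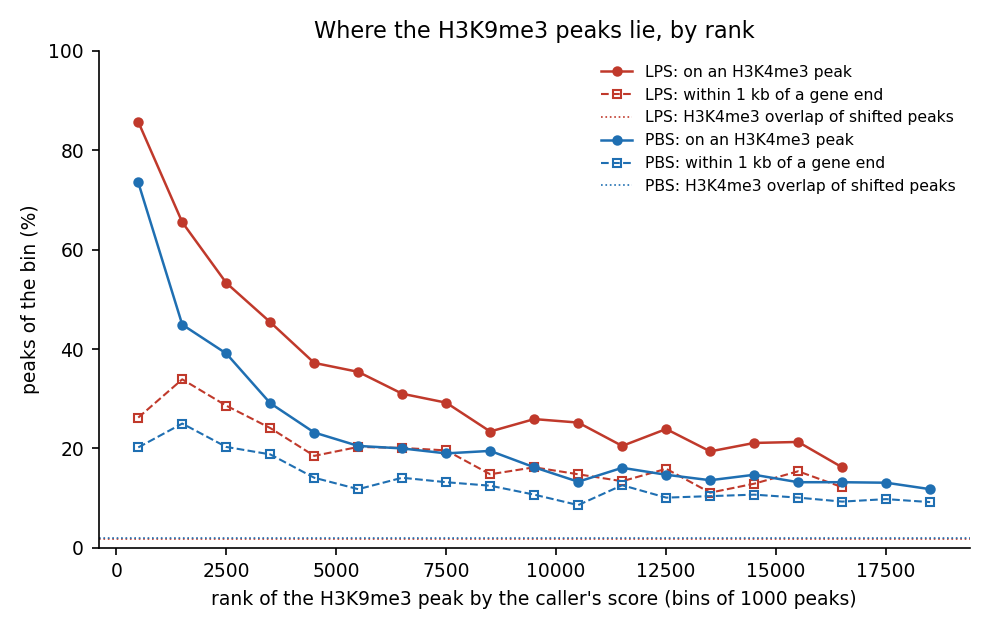
Share of H3K9me3 peaks (y axis, percent) that lay on an H3K4me3 peak of the same treatment (filled circles) or within 1 kb of a gene end (open squares), in bins of 1000 peaks ranked by the caller's score (x axis), for LPS in red and PBS in blue. Dotted lines give the overlap after random shifts (1.77% in LPS and 1.97% in PBS); the share on H3K4me3 starts at 85.7% and 73.5%.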

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

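The alternatives were planned, except those for gene bodies, wide peaks, merged regions, matching on tags per covered kb and gene ends for the overlap of the marks, which were chosen after seeing the data. No paired analysis was possible because each group had 1 library, so no result comparing LPS with PBS came from a test between groups. The cause of a change was not tested unless a sentence gives it. Counts of unmatched peaks stayed within 1.5 times under 50% coverage, a distance of 1 kb and lists of equal length. With equal lengths they were 6570 in PBS and 6235 in LPS for H3K4me3, and 11389 and 11415 for H3K9me3. Equal lengths hold the 2 counts close together in advance, so this setting cannot show whether PBS had an excess. Scores of at least 100 in both lists gave 916 LPS-only and 3872 PBS-only peaks for H3K4me3 and 1586 and 1460 for H3K9me3, and in the counted list alone 316 and 1215, and 725 and 655, with fewer peaks counted. With that score in both lists, LPS-only promoters fell to 174 while PBS-only promoters rose from 685 to 801, and LPS-only and PBS-only promoters came to 69 and 287 in the counted list alone. The median H3K4me3 ratio was -0.313 with regions merged within 1 kb, -0.339 at scores of at least 100 and -0.154 per covered kb, and the H3K9me3 median reversed to -0.029 per covered kb. Regions past 2-fold in H3K4me3 numbered 267 (LPS) and 155 (PBS) with the median region at 0, 1 and 12 per covered kb, and 165 in LPS with no tag minimum. In H3K9me3 they numbered 0 and 1 per covered kb and 365 and 219 with no tag minimum, and 39 in PBS with regions merged within 1 kb. H3K4me3 peaks with both marks numbered 1415 (LPS) and 947 (PBS) when 50% had to be covered, 1460 and 1049 at scores of at least 100, and 2874 and 2211 within 1 kb of gene ends; LPS exceeded PBS each time. The number of H3K4me3 lists in the outer 5% ran from 6 to 7, but its members changed. Per covered kb antigen presentation (percentile 29.9), T cell markers (38.3) and Hox genes (87.5) left it. Inflammatory mediators (99.7), NF-kB signalling (0.43) and LPS-linked metabolism (0.17) entered it. Interferon-stimulated, neuronal and zinc finger genes stayed in it under every setting. Per covered kb the medians of antigen presentation (-0.025) and T cell markers (-0.019) reversed. Single promoters were checked for 57 of the genes that the naming rule takes. Where the counting interval lay off 0, their ratios reversed per covered kb at Ccl7 (0.23), Irak2 (-0.79), B2m (0.0395), H2-DMa (-0.59), Nlrc5 (-0.53), Wt1 (0.0402), Hmox1 (0.18), Ctsl (0.22), Chmp2a (-0.52), Pdgfrb (-0.13), Slc17a7 (-0.39), Hoxa10 (-0.14) and Hoxb8 (-0.39). With the median promoter at 0, Sun1 (0.0444) and Spag4 (0.0812) reversed, and over merged regions H2-Ab1 (0.0227) and Chmp2a (-0.69). Of these 57 promoter ratios, 14 had the opposite sign per covered kb, 6 with the median promoter at 0 and 2 over merged regions. The 57 are not all the promoters that the naming rule takes, so these counts do not cover every change of sign. Depth limits weak peaks most: a median unmatched H3K9me3 peak had 15 to 16 tags.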

Other observations

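The widest H3K4me3 peaks, chosen after their values were seen, were compared between the treatments. In LPS they included those at Tcirg1 with Ndufs8 (8.13 kb, 1214 tags, against 1475 in PBS), Niban2 (7.86 kb, 1074 tags, against 1507), the interleukin 4 receptor gene Il4ra (7.47 kb, 853 tags, against 868) and the tumour necrosis factor receptor gene Tnfrsf1a (7.35 kb, 929 tags, against 1184). In PBS the widest was at Stat6, the transcription factor of interleukin 4 signalling, and its neighbour Nab2 (8.53 kb, 1272 tags), with 941 tags over 6546 bp in LPS. The PBS peak at Rhog (8.07 kb, 1129 tags) had no LPS counterpart. A peak of 8.23 kb with no coding gene end nearby, on chromosome 13 (119595412 to 119603644) held 2415 tags in LPS and 2535 in PBS, and an H3K9me3 peak lay on it.

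All tests in the following paragraphs and their bounds were chosen after the results were seen. The first pattern is that wide H3K4me3 peaks with many tags were listed under 1 treatment only, as at Ppp1r9b, Tnfaip2 and Spi1 in LPS and Git1 and Zc3h12a in PBS. For the LPS-only peaks a difference in depth is argued against, because 45 LPS peaks of at least 200 tags had no counterpart in the deeper PBS library. At each width more PBS peaks of that size were unmatched (20 up to 2 kb, 56 at 2 to 4 kb and 27 above 4 kb) than LPS peaks (1, 30 and 14). A difference in depth therefore stays open for the PBS-only peaks. Among peaks of at least 200 tags, the unmatched share rose with width in LPS from 0.0371% up to 2 kb to 3.58% above 4 kb, and in PBS from 0.460% to 4.73%. Above 4 kb the unmatched peaks had median scores of 136.7 in LPS and 98.3 in PBS, against 277.0 and 361.5 for matched ones, which stood at 723 and 826 up to 2 kb. The local background of the caller, which without a control library is estimated within 10 kb of the peak itself, is a candidate explanation. These values do not establish it, because unmatched peaks can be likelier near the caller's threshold, and so score lower, under other causes too. An effect of LPS at single genes stays open, untested.

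The second pattern is that H3K9me3 peaks of the highest scores lay on H3K4me3 peaks. Away from gene ends the median log2 ratio of H3K4me3 to H3K9me3 tags per kb, scaled to the filtered totals, was -0.75 in LPS (interval -0.79 to -0.71) and -0.92 in PBS (-0.96 to -0.88), and at gene ends 1.07 (0.96 to 1.16) and 1.205 (1.11 to 1.29), which leaves high-copy sequence collapsed in the reference open, because the peaks measured were chosen for signal in both libraries. Away from gene ends the share of H3K4me3 peaks with H3K9me3 was 1.44 times (LPS) and 1.32 times (PBS) higher in the densest than in the least dense quintile, but it fell over the first 4 quintiles (from 16.3% to 13.0% in LPS and from 12.01% to 6.33% in PBS), so background signal at H3K4me3-rich chromatin stays undecided there. At gene ends that factor was 5.99 in LPS and 6.30 in PBS, consistent with such a background. No biological explanation was tested, and true sites of both marks, as at imprinted genes, stay open.

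The third pattern is that more of the LPS than of the PBS H3K9me3 list lay on H3K4me3 peaks. The difference in list length is argued against, since 17369 peaks of each list still differed by 10.2 percentage points (33.7% and 23.5%). A base composition or gene density bias of the library could act on all peaks. Across the 19 autosomes, the log2 ratio of LPS to PBS peaks more than 5 kb from genes and off H3K4me3 peaks went with gene density at Spearman's rho of 0.35 (permutation p = 0.149, Benjamini-Hochberg adjusted 0.149) and Pearson's r of 0.48 (permutation p = 0.0380, adjusted 0.0761, 2 relations computed; 0.50 without chromosomes 7 and 11), so this bias cannot be told apart from an effect of LPS, because neither coefficient passes 0.05 after adjustment and each treatment had 1 library. Whether the LPS-only H3K9me3 at Hox genes goes with this pattern was not tested.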
